A study of Mus musculus with 4 samples.

How the data were processed

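Single-cell RNA sequencing was performed on lymphocytes from the kidneys of female NZB/W F1 mice, a hybrid strain that develops a lupus-like autoimmune nephritis. The nephritis here was driven with poly(I:C), a synthetic double-stranded RNA that provokes type I interferon. Cells reached by an antibody against CD45.2 given into the blood were excluded per the labels, so the sort was aimed at cells of the tissue. How complete that exclusion was is not measured here. The sort took live CD45-positive cells that lacked CD3, CD5, CD19 and Ly6g and carried NK1.1, a surface receptor of NK cells and type 1 innate lymphoid cells (ILC1s). Of the 4 samples of the series, 2 are analysed here. These are the library from mice given poly(I:C) with an isotype control antibody and the library from mice given poly(I:C) with an antibody that blocks NKp46, an activating receptor of these cells. The healthy and the poly(I:C) libraries sorted on both NKp46 and NK1.1 are not analysed here. Both analysed libraries carry an age of 25 in a label without a unit. Per the labels' protocol, 3 mice received anti-NKp46 and 8 mice were nephritic, without saying how the 8 were divided between the nephritic libraries. Each group therefore had 1 library, made from pooled animals or from animals that cannot be told apart.

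The authors deposited raw UMI counts per gene and cell barcode for each library, with barcodes already filtered, since the lowest total was 500 UMIs in the isotype library and 501 in the anti-NKp46 library. A UMI is a molecular tag that lets PCR copies of 1 transcript be counted once. Libraries were made with a 10x Genomics kit that reads the 5′ end of transcripts, per the labels' protocol. The submitters' processing notes name Cell Ranger 5.0.0 and the mouse build mm10. The annotation and the settings for calling cells are not given in the sources used here. Per the labels' protocol, kidneys were minced, digested with collagenase and DNase at a warm temperature and passed through density gradients before the cells were sorted. These steps can induce stress genes. Reads of near-identical or overlapping genes can be split between them by the counting, so values of the Ly49 (Klra) receptors, the Bcl2a1 genes, Ifit3 with Ifit3b, the H2-Q genes and AY036118, which lies inside Gm42418, are uncertain.

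Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs. Doublets were called per library with Scrublet as implemented in Scanpy, at an expected rate of 5%, and removed. It marked 1 isotype and 11 anti-NKp46 barcodes, 0.226% of those that passed the filter. With so few marked against the expected 5%, droplets with 2 cells cannot be taken as removed. The word cell means a barcode throughout. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen after leaving out ribosomal, mitochondrial, immunoglobulin and T cell receptor segment genes and the genes of lists that describe cell states. Clustering used 30 principal components, 15 neighbours and the Leiden method at resolution 0.6, without integration. Clusters were named from 16 marker classes. A cluster took a class name when at least 3 of its markers were 2-fold or more above the other cells, with 10 CPM added to both levels, in at least 10% of its cells. The class had to have more such markers than any other, and at least as many of the 10 leading genes as all other classes together. The markers were fixed before the data were examined and this naming rule was written after the clusters were seen. Innate lymphoid cells were all cells outside the clusters named T-like, macrophage-like or tubule-like. The ILC1-like class joined 2 clusters and the NK-like class was 1 cluster.

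Raw counts were summed over the cells of a population in each library and scaled to the total of that population and library (CPM). A ratio is anti-NKp46 over isotype and is given on the log2 scale. Intervals are at 95%. They are exact Poisson intervals for a level, exact conditional binomial intervals for a ratio, Clopper-Pearson intervals for a share and Newcombe intervals for a difference of shares. For the median of a gene list the interval comes from 1000 draws of the counts. All of them cover counting error only, not the variation between mice, and UMIs from 1 cell are not independent of each other. With 1 library per group there was no test and no p-value, and every difference compares these libraries, not the treatments. Where a count was 0 the upper limit is what 3 counts would give.

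The gene lists, the named genes rule and the alternative settings other than those named as chosen later were fixed before the data were examined. For all innate lymphoid, ILC1-like and NK-like cells, the rule took the 10 genes highest and the 10 lowest by the interval bound nearest to no change, among genes of at least 50 CPM in 1 library and at least 100 UMIs in both together. Ribosomal, mitochondrial, haemoglobin, immunoglobulin and T cell receptor segment genes and unnamed gene models were left out of that rule. A fixed set of 23 genes, including Ncr1, which encodes NKp46, and Csf2, was reported whatever its values, with 2 to 4 members of each described list. The 22 lists were NKp46 signalling, effector cytokines and chemokines, cytotoxic granule, immediate early genes, heat shock genes, NF-kB response, type I interferon response, interferon-gamma response, MHC class I, cell cycle, tissue residency, circulating and mature NK, inhibitory receptors, Ly49 and NKG2 receptors, cytokine receptors, TGF-beta response, glycolysis, oxidative phosphorylation, Myc and mTORC1 targets, tissue repair mediators, innate lymphoid transcription factors, and apoptosis and survival. A member was measured at 20 CPM or more averaged over both libraries. It was counted as higher or lower at 1.5-fold or more with an interval that excluded no change, which is a rule of size and no test. Each list's median was placed among the medians of 10000 random lists of the same size matched on expression in 25 bins, as a description of these libraries. Shares of cells with a UMI were computed after thinning each cell to 1000 UMIs, with shallower cells left out.

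The ratio and list steps were tested on simulated counts with the libraries' own sizes and 200 genes changed by known amounts. Of the 2-fold changes, 100% were called in the right direction among 3421 genes of innate lymphoid cells, 100% among 3497 genes of ILC1-like cells and 84.9% among 3237 genes of NK-like cells. Of the 1.5-fold changes, which lie at the size the list counts use, 45%, 50% and 42.1% were called in the right direction in these populations. The intervals held the true ratio for 95.5%, 95.8% and 95.9% of these genes. The simulated counts were Poisson draws, the model that the intervals assume, so this coverage checks the code only. It says nothing about UMIs that are not independent within a cell, or about genes averaging under 50 CPM, which were left out.

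The alternatives were TMM factors from edgeR, a total without ribosomal, mitochondrial and the 20 most abundant genes, the mean of per-cell CPM, thinning to 1000 UMIs, no filter, a stricter filter of 1000 UMIs, 500 genes and 5% mitochondrial UMIs, doublets kept, Leiden resolutions 0.3 and 1.0, clustering with the list genes, centring each gene per library, classing innate lymphoid cells by the sign of a marker score, and list members at 5 or 100 CPM. A further 8 alternatives were chosen after seeing the data. Gene coordinates are from GENCODE M21 for GRCm38 (mm10), to which 32158 of the 32285 gene identifiers in the tables (99.6%) matched. The software was Python 3.11.15 with Scanpy 1.11.5, anndata 0.12.19, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and Matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.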

Results

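Kidney innate lymphocytes carrying NK1.1 were profiled by single-cell RNA sequencing in lupus-prone NZB/W F1 mice with poly(I:C) nephritis, after an isotype control antibody or an antibody that blocks NKp46. The comparison addresses whether blockade of NKp46, an activating receptor encoded by Ncr1, alters kidney ILC1s and their output of Csf2, the macrophage growth factor GM-CSF. The isotype library held 3487 barcodes and 8482694 UMIs, with a median of 2077 UMIs and 1119 genes per barcode. The anti-NKp46 library held 1839 barcodes and 5248197 UMIs, with a median of 2847 UMIs and 1518 genes. After filtering, 3481 and 1820 cells remained. The anti-NKp46 library was deeper per cell and more spread, since 16.0% of its cells held under 1000 UMIs against 4.08% in the isotype library. Ribosomal protein genes took a median of 14.5% of a cell's UMIs with anti-NKp46 and 19.7% with isotype. There was 1 library per group, so no difference has a replicate check.

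ILC1-like cells made up a larger share of the anti-NKp46 library and NK-like cells a smaller one. ILC1-like cells were 1052 of 1820 (57.8%, 55.5 to 60.1) with anti-NKp46 and 940 of 3481 (27.0%, 25.5 to 28.5) with isotype, 30.8 percentage points higher (28.1 to 33.5). NK-like cells, a cluster led by the mast cell protease Cma1, the egress receptor S1pr5 and the maturation receptor Klrg1, were 98 cells (5.38%, 4.39 to 6.52) with anti-NKp46 and 809 (23.2%, 21.8 to 24.7) with isotype. That difference was −17.9 points (−19.6 to −16.1). The class was 1 cluster and left out the unnamed clusters 0 and 4. Classing every innate lymphoid cell by a marker score gave 31.5% with anti-NKp46 and 47.1% with isotype as NK-like. The cycling cluster, led by the histone Hist1h1b and the proliferation antigen Mki67, held 7 cells (0.385%) with anti-NKp46 and 68 (1.95%) with isotype.

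The ILC1-like cells formed 2 clusters, of which cluster 1 took a similar share of both libraries and cluster 3 did not. Cluster 1, led by the IL-7 receptor Il7r, the IL-2 receptor chain Il2ra, the adhesion receptor Crtam and Tmem176b, held 454 anti-NKp46 cells (24.9%) and 879 isotype cells (25.3%). Cluster 3, led by the chemokine receptor Cxcr6, the keratin Krt83, the adhesion receptor Cd226 and the NKG2A gene Klrc1, held 598 anti-NKp46 cells (32.9%) and 61 isotype cells (1.75%). A cluster drawn almost wholly from 1 library may be that library rather than a cell type. Within cluster 1 alone Cxcr6 was also higher with anti-NKp46, at 720.4 against 346.5 CPM. Median depth in cluster 1 was 1208 UMIs with anti-NKp46 and 1800 UMIs with isotype, and in cluster 3 it was 3073 and 1813 UMIs.

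Clusters 0 and 4 stayed unnamed. Cluster 0, led by the granzymes Gzmb and Gzmk, the protease Htra3 and Cd3g, held 12.4% of anti-NKp46 and 12.1% of isotype cells, a difference within counting error. Cluster 4, led by the trypsinogen Prss2, the transcription factors Tcf7 and Eomes and Cd3d, held 20.1% and 26.0%. Macrophage-like cells, marked by the complement genes C1qa, C1qb and C1qc and the lysozyme Lyz2, were 22 (1.21%) with anti-NKp46 and 255 (7.33%) with isotype. T-like cells, with Cd3e and Trac, were 2.53% and 2.04%, and 4 and 12 cells were tubule-like. The sort excluded CD3-positive cells and took NK1.1-positive cells. Innate lymphoid cells came to 1748 (96.0%) with anti-NKp46 and 3143 (90.3%) with isotype. The ILC1-like difference was 19.5 points at a finer clustering resolution, and the NK-like difference lay between −22.7 and −7.98 points depending on how the cells were clustered. Classing innate lymphoid cells by a marker score gave 64.5% and 43.1% of all cells as ILC1-like, with 507 of 4891 cells (10.4%) within 0.1 of the score's boundary.

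**Figure D1:**
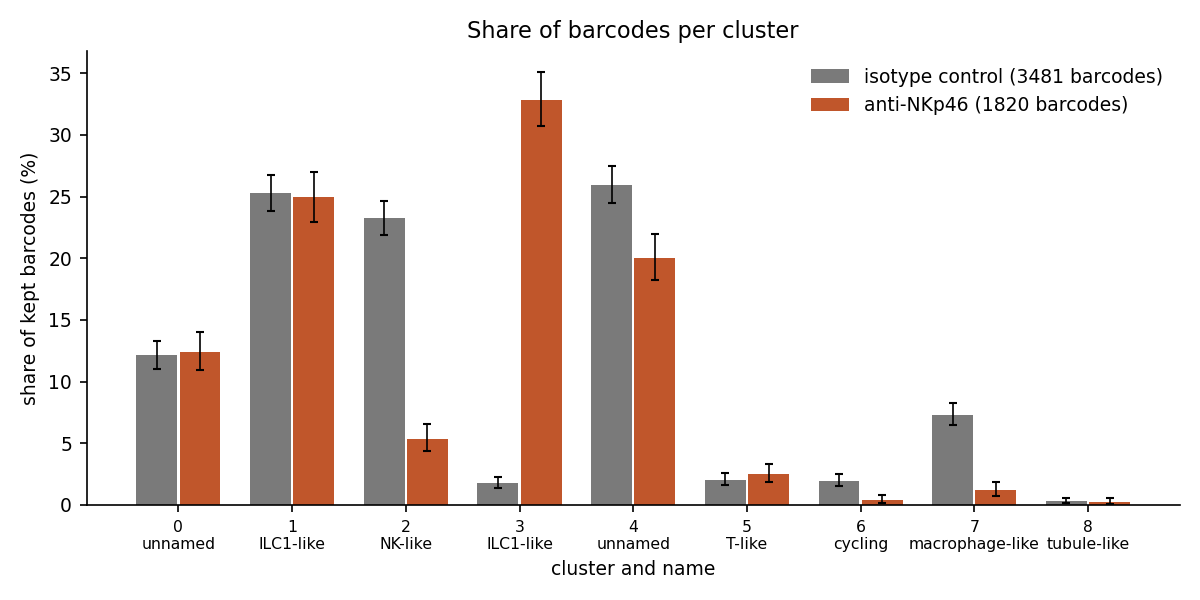
Share of all kept cells in each cluster, in percent, for the isotype and anti-NKp46 libraries, with exact 95% binomial intervals that cover counting error only. Cluster 3 held 32.9% of anti-NKp46 cells and 1.75% of isotype cells, and the NK-like cluster 2 held 5.38% and 23.2%.

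Ncr1 transcripts remained present with anti-NKp46, with differences under 1.5-fold in ILC1-like and NK-like cells, and Csf2 transcripts were fewer. Ncr1 (ENSMUSG00000062524, chromosome 7, 4337724 to 4345164, plus strand, GRCm38) stood at 2195 CPM with anti-NKp46 and 1862 CPM with isotype in innate lymphoid cells, a log2 ratio of 0.24 (0.20 to 0.27). In ILC1-like cells the ratio was 0.43 (0.37 to 0.49) and in NK-like cells −0.16 (−0.28 to −0.03). Csf2 (ENSMUSG00000018916, chromosome 11, 54247271 to 54249667, minus strand) had 47 UMIs, 9.45 CPM (6.94 to 12.6), with anti-NKp46. With isotype it had 324 UMIs, 44.4 CPM (39.7 to 49.5), and the ratio was −2.23 (−2.71 to −1.79). ILC1-like cells held 39 and 203 of these UMIs, at 14.9 and 106.5 CPM, a ratio of −2.84 (−3.37 to −2.34). All of the isotype library's ILC1-like Csf2 UMIs lay in cluster 1, where the level was 34.2 CPM with anti-NKp46 and 114.2 CPM with isotype, a ratio of −1.74 (−2.38 to −1.16). The cycling cluster held a further 105 isotype Csf2 UMIs, in 3 of its 68 cells.

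Csf2 came from few cells. In the isotype library 71 of 3143 innate lymphoid cells had any Csf2 UMI, and 3 of them held 165 of the 324 UMIs. Without the 3 cells richest in Csf2 in each library the ratio was −1.91 (−2.53 to −1.33) over innate lymphoid cells and −2.81 (−3.56 to −2.12) in ILC1-like cells. At a matched depth of 1000 UMIs, 11 of 865 ILC1-like cells (1.27%, 0.636 to 2.26) had a Csf2 UMI with anti-NKp46 and 34 of 893 (3.81%, 2.65 to 5.28) with isotype, a difference of −2.54 points (−4.10 to −1.08). Within cluster 1, which held all 34 of these isotype cells, the shares were 5 of 285 (1.75%) and 34 of 837 (4.06%), and their difference of −2.31 points (−4.16 to 0.247) was not detectable at this depth. Without thinning the ILC1-like shares were 2.19% and 5.53%. Over all innate lymphoid cells the thinned shares were 0.954% and 1.38%, and their difference was not detectable at this depth. NK-like cells served as background. At 1000 UMIs, 0 of 80 with anti-NKp46 and 0 of 795 with isotype had a Csf2 UMI. That allows a share of cells with a UMI of up to 3.75% and 0.377%. Before thinning, the median depths of NK-like cells were 2739 and 2078 UMIs. Without thinning 1 of 98 anti-NKp46 NK-like cells had a Csf2 UMI. Other cells were not free of it, since thinned T-like cells had a Csf2 UMI in 1 of 41 (2.44%) with anti-NKp46 and 2 of 64 (3.13%) with isotype, and thinned macrophage-like cells in 0 of 17 and 4 of 230 (1.74%). Thinning left out 187 anti-NKp46 and 47 isotype ILC1-like cells.

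A Ncr1 UMI was found in 88.9% (86.6 to 90.9) of thinned ILC1-like cells with anti-NKp46 and in 78.6% (75.8 to 81.3) with isotype, and without thinning in 93.3% and 92.2%. In thinned NK-like cells the shares were 87.5% and 86.3%, a difference within counting error. In the unnamed cluster 0 they were 82.2% and 72.7%, and in cluster 4 they were 71.9% and 76.6%. Tubule-like cells, which should lack Ncr1, had 1 thinned cell with a UMI among 9 in the isotype library and 0 of 2 with anti-NKp46. Before thinning, the median depths of tubule-like cells were 1408 UMIs with isotype and 3905 UMIs with anti-NKp46. The ILC1-like Csf2 ratio depended on the clustering. It was −0.54 when the barcodes called as doublets were kept and −0.70 when cells were clustered with the list genes, with −1.10 over innate lymphoid cells thinned to 1000 UMIs.

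In ILC1-like cells, interferon-induced and heat shock genes were higher with anti-NKp46 and Ccl1 was lower. NF-kB response genes were lower over the class, but few of them were counted as lower within either of its clusters. Of 34 measured type I interferon response genes, 27 were higher and 0 lower, with a median log2 ratio of 0.91 (0.79 to 1.01). Ifit3 (2.54), Ifit1 (2.53) and Ifi44 (2.16), all antiviral effectors, had the highest ratios of the list, and the ubiquitin-like Isg15 stood at 154.2 against 55.1 CPM (1.48). The chemokine Cxcl10, which recruits CXCR3-bearing lymphocytes, was at 189.0 CPM with anti-NKp46 and 44.6 CPM with isotype (2.08, 1.75 to 2.43), but it was −0.99 when cells were clustered with the list genes and −2.44 in cluster 3 alone. Of 26 interferon-gamma response genes 13 were higher and 1 lower (median 0.56), among them the GTPases Gbp6 (1.83) and Iigp1 (1.82). MHC class I genes had a median of 0.47, with 3 of 9 higher, including the nonclassical H2-T23 (0.74), and the shared light chain B2m at −0.27.

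Heat shock genes were higher in 7 of 11 measured (median 0.63, 0.55 to 0.79), including the chaperones Hsph1 (163.0 against 57.7 CPM), Dnaja1 (1.23) and Hspa8 (1.04). The cold-inducible RNA-binding gene Rbm3 was lower, at 247.2 against 889.6 CPM (−1.85), in the same cells. Such a gap in temperature-responsive genes ran through the other clusters as well. Hsph1 ratios lay between 1.22 and 2.01 and Rbm3 ratios between −2.37 and −0.92 in clusters 0 to 7. With 1 library per group, a difference in the handling of the libraries was not separated from the antibody for these genes.

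NF-kB response genes were lower in 9 of 20 and higher in 1 over ILC1-like cells (median −0.41, −0.57 to −0.30). Within cluster 1 they were lower in 1 and higher in 2 of 20 (−0.09, −0.21 to 0.03), and within cluster 3 lower in 2 and higher in 0 of 18 (0.04). Cd83, an activation marker (−3.34, −3.99 to −2.74), Relb, a subunit of NF-kB (−1.03), its feedback inhibitor Nfkbia (−0.94) and the adaptor Traf1 (−0.84) were among them. The chemokine Ccl1, a ligand of CCR8, was at 274.0 CPM with anti-NKp46 and 1723 CPM with isotype (−2.65, −2.77 to −2.54). Xcl1, which attracts cross-presenting dendritic cells, was at 2419 and 4342 CPM (−0.84). Cd74, the MHC class II invariant chain (−1.83), H2-Aa (−1.80), the actin-capping gene Capg (−2.20) and the granzyme Gzmc (−1.73) were also lower. The macrophage-like cluster held Cd74 and H2-Aa at high levels, and a UMI of 6 other macrophage genes, such as C1qa and Lyz2, was seen in 3.72% of anti-NKp46 and 5.28% of isotype innate lymphoid cells. Without those cells the ratios were −1.66 for Cd74 and −1.59 for H2-Aa. Of 16 Myc and mTORC1 targets 7 were lower and 0 higher (median −0.46), for example the spermidine synthase Srm (−1.09), the nucleolar Npm1 (−0.82) and the polyamine enzyme Odc1 (−0.81).

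Effector cytokines and chemokines went both ways in ILC1-like cells, with 3 higher and 3 lower of 16 (median −0.02), and of 16 cytotoxic granule genes 3 were higher and 1 lower (0.10). Granzyme Gzma stood at 612.6 against 293.9 CPM (1.06, 0.92 to 1.20), perforin Prf1 at 336.3 against 201.0 CPM (0.74) and Tnf at 180.2 against 108.1 CPM (0.74). The transcription factor Tbx21, which specifies type 1 lymphocytes, had a ratio of 0.88 (0.72 to 1.04), its upstream receptor chain Il12rb2 one of 0.90, and Ifng one of 0.48 (0.30 to 0.66), under the 1.5-fold rule. Gzmb (−0.24), Ccl5 (−0.36), Ccl3 (−0.02), Ccl4 (0.17), Klrb1c, which encodes NK1.1 (0.36), Il18r1 (−0.01), Tnfsf10 (−0.02) and Cd200r1 (0.27) also differed by less than 1.5-fold. Tissue residency genes were higher in 5 of 10 and lower in 1 (median 0.49), with the integrin Itga1 at 1.32, the transcription factor Runx3 at 1.02 and the activation antigen Cd69 at −0.96. The fibrinogen-like immunoregulator Fgl2 (1.37), the creatine kinase Ckb (1.53), the ribonuclease Rnaset2a (1.75), Ccdc92 (1.76) and the endosomal Plekhf1 (1.76) completed the genes named by the rule as higher, with AY036118. The NK-associated Eomes (−1.27) and Itga2 (−1.30, from 28 UMIs in all) were lower.

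Cxcr6 (1.18), Il7r (−0.84), Crtam (−2.18) and Ccdc184 (−3.20) lead clusters 1 or 3, so their ratios over ILC1-like cells partly restate the mix of those clusters. Within cluster 1 they were 1.06, −0.24, −0.64 and −1.93. Cluster 3 took 598 anti-NKp46 and 61 isotype ILC1-like cells, so ratios within cluster 1 may compare unlike subsets. Cluster 1 also differed in depth, with 169 of 454 anti-NKp46 and 42 of 879 isotype cells under 1000 UMIs. Within cluster 1 the interferon median was 1.66, with Cxcl10 at 3.79, and within cluster 3 it was 0.18, with Ifit3 at −0.67, Cd74 at 0.63, H2-Aa at 1.07 and Itga1 at −0.43. The Myc and mTORC1 median was −0.13 (−0.28 to 0.04) in cluster 1, with 1 of 17 lower, and −0.30 in cluster 3, with 3 of 15 lower. Tissue residency stood at 0.14 (−0.13 to 0.37) in cluster 1, with 2 of 10 higher, and at −0.22 in cluster 3, with 1 higher and 2 lower of 11. Gzma, Prf1 and Tnf had ratios of 0.87, 0.73 and 0.87 in cluster 1 and of 0.48, 0.35 and 0.10 in cluster 3. Ccl1 was −1.03 in cluster 1, and Itga2 was 0.37 after thinning.

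**Figure D2:**
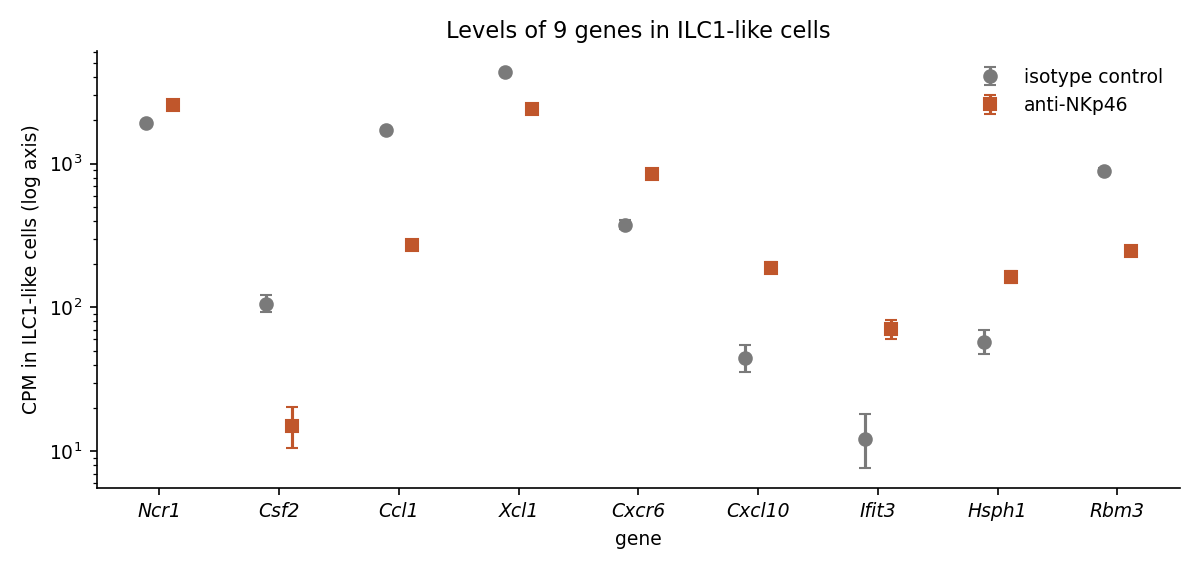
Levels in CPM, on a log axis, of 9 genes in ILC1-like cells of the isotype and anti-NKp46 libraries, with 95% intervals that cover counting error only. Csf2 was at 106.5 CPM with isotype and 14.9 CPM with anti-NKp46, and Ccl1 at 1723 and 274.0 CPM.

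Across all innate lymphoid cells, interferon-induced genes, heat shock genes and Cxcr6 were higher with anti-NKp46, and mature NK and cell cycle genes were lower. Both lower lists turned direction with clusters weighted as in the isotype library, to medians of 0.31 and 0.18, and cell cycle genes also did after thinning (0.10) and as a mean of per-cell CPM (0.11). Cxcl10 stood at 113.8 CPM with anti-NKp46 and 16.3 CPM with isotype (2.80, 2.51 to 3.10), Ifit3 at 57.1 and 7.95 CPM (2.84, 2.43 to 3.28), and the antiviral synthetase Oas1a at 53.1 and 16.5 CPM (1.69). Isg15 (1.65), the GTPase Gbp6 (86.0 against 22.1 CPM) and the virion tether Bst2 (1.48) were higher too, as was the chaperone Hsph1 (1.61). Cxcr6 was at 465.1 and 119.4 CPM (log2 interval 1.85 to 2.08) and Krt83 at 182.9 and 64.5 CPM. Among the lowest, Hist1h1b had 8.44 against 80.6 CPM (−3.26, −3.74 to −2.80) and Ccl1 145.7 against 574.8 CPM (−1.98). Rbm3 (−1.72), the microtubule regulator Stmn1 (−1.70), the secreted glycoprotein osteopontin, Spp1 (−1.52), the granzyme inhibitor Serpinb9b (−1.51), Capg (−1.47), the NK maturation genes Klrg1 (−1.39) and Klf2 (−1.15) and the topoisomerase Top2a (−1.30) followed.

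Other genes fixed in advance gave smaller ratios over innate lymphoid cells. Tnf was at 145.9 against 72.1 CPM (1.02, 0.85 to 1.18), Tbx21 at 0.75 and Cd200r1 at 0.86 on the log2 scale. Ccl5 was lower, at 4780 against 8687 CPM (−0.86), and so was Itga2 (−1.15). Ifng (0.42), Tnfsf10 (0.44), Il12rb2 (0.51), Itga1 (0.57), Il18r1 (0.24), Klrb1c (0.13), Il7r (0.06), Xcl1 (−0.18), Ccl4 (−0.17), Ccl3 (−0.25), Gzma (−0.28), Gzmb (−0.35), Eomes (−0.36) and Prf1 (−0.58) stayed under 1.5-fold. Areg, a repair growth factor, had 7 and 16 UMIs (−0.64, −2.16 to 0.72).

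Type I interferon response genes were higher in 24 of 34 measured and lower in 0, with a median of 0.87 (0.79 to 0.95), above all 10000 random lists. Interferon-gamma response genes were higher in 12 of 25 (median 0.53), with Igtp at 1.34, and MHC class I genes in 2 of 9 (0.55), with H2-T22 at 0.70. Heat shock genes were higher in 7 of 10 (0.69, 0.64 to 0.74), among them Dnaja1 (1.17) and Hspa8 (1.01). Innate lymphoid transcription factors were higher in 6 and lower in 1 of 23 (0.42), with the residency factor Zfp683 at 1.31, the Helios gene Ikzf2 at 0.89 and the Wnt effector Lef1 at −0.88. Circulating and mature NK genes were lower in 7 and higher in 2 of 14 (−0.71, −0.82 to −0.59), with Cma1 at −1.70 and the monocyte-lineage antigen Ly6c2 at 0.90. Cell cycle genes were lower in 9 and higher in 0 of 17 (−0.69, −0.86 to −0.45), with Mki67 at −2.58 and the ribonucleotide reductase Rrm2 at −1.92.

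The median over all genes was 0.14 in innate lymphoid, 0.17 in ILC1-like and 0.05 in NK-like cells, and −0.02, 0.02 and −0.04 with TMM factors, so list medians below about this size carry no direction. Smaller list medians over innate lymphoid cells were 0.31 for inhibitory receptors (3 of 10 higher, Entpd1 at 0.88), 0.25 for cytokine receptors (3 of 18 higher, Il21r at 0.90) and 0.18 for NKp46 signalling (0 of 15 either way). Tissue residency stood at 0.17 (2 of 11 higher), TGF-beta response at 0.12 (1 higher and 3 lower of 9), glycolysis at 0.11 (2 of 14 higher) and immediate early genes at 0.10 (2 higher and 1 lower of 20). Apoptosis and survival (0.09, 0 of 13 either way) and NF-kB response genes (0.01, 0 of 18 either way) lay near 0. Ly49 and NKG2 receptors (−0.16, 3 higher and 5 lower of 18) and Myc and mTORC1 targets (−0.16, 2 of 16 lower) were below it. So were effector cytokines and chemokines (−0.07, 3 higher and 3 lower of 15), cytotoxic granule genes (−0.06, 2 of 17 lower), oxidative phosphorylation (−0.06, 0 of 21 either way) and tissue repair mediators (−0.04, 1 higher and 2 lower of 6).

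With clusters weighted as in the isotype library, Stmn1 was at 0.29 and Cd200r1 at −0.00. In that weighting Klrg1 (−0.06), Klf2 (−0.11), Top2a (−0.05), Ccl5 (−0.14) and Cxcr6 (0.81) were also closer to 0, while the interferon median was 0.88.

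**Figure D3:**
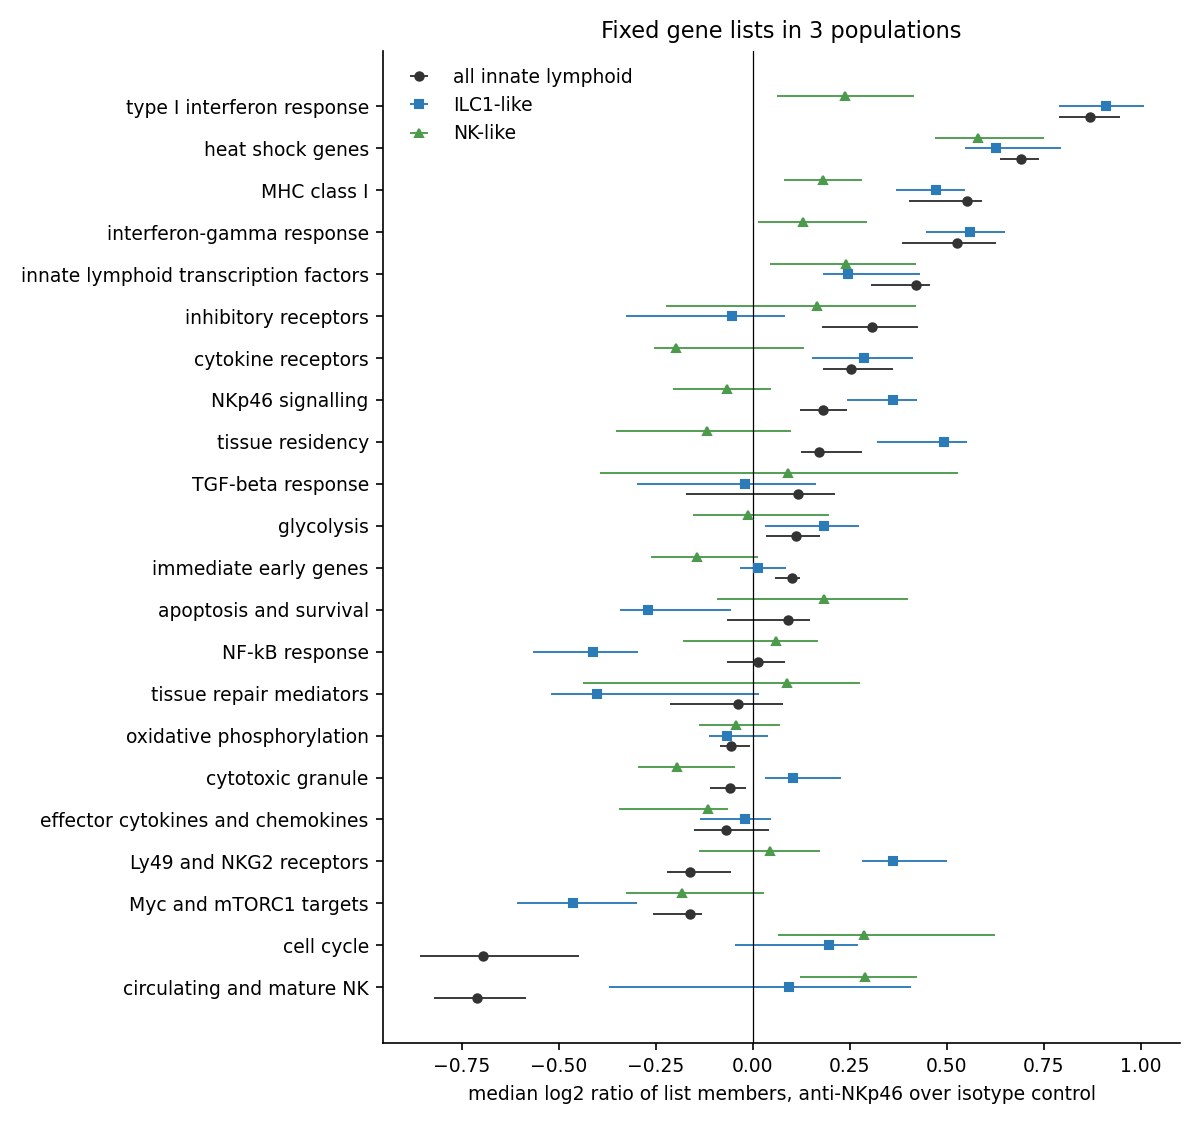
Median log2 ratio of anti-NKp46 over isotype for the 22 gene lists in innate lymphoid, ILC1-like and NK-like cells, with 95% intervals from counting error. The type I interferon median was 0.87, 0.91 and 0.24 and the heat shock median 0.69, 0.63 and 0.58 in these populations.

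The interferon difference varied by cluster and the heat shock difference did not vary in direction. The type I interferon median was 1.66 (1.47 to 1.72) in cluster 1, 0.82 in cluster 4 and 0.76 in cluster 0, and 0.24 and 0.18 in the NK-like cluster 2 and in cluster 3. The cluster 3 value (−0.03 to 0.45) rested on 61 isotype cells. Classing cells by marker score or centring genes per library brought the ILC1-like and NK-like medians close to each other. In macrophage-like, T-like and cycling cells the interferon median was 0.52, 0.21 and −0.11. Heat shock medians were 0.73 (0.61 to 0.83) in cluster 1, 1.08 in cluster 3, 0.83 in cluster 4, 0.76 in cluster 0 and 0.95 in macrophage-like cells.

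**Figure D4:**
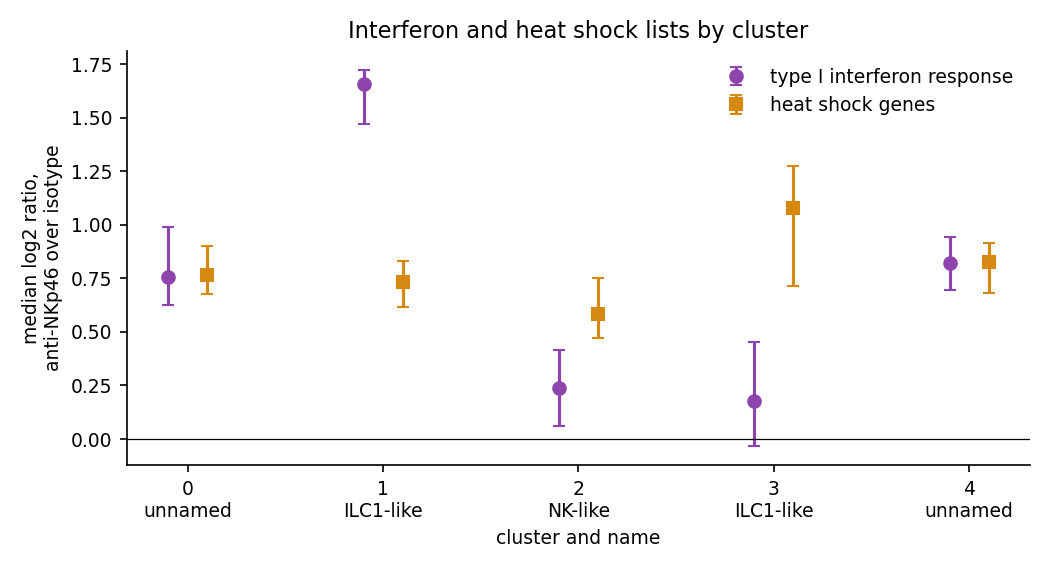
Median log2 ratio of the type I interferon and heat shock lists in clusters 0 to 4, with 95% intervals from counting error. In clusters 0 to 4 heat shock medians lie between 0.58 and 1.08, and interferon medians range from 0.18 in cluster 3 to 1.66 in cluster 1.

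In NK-like cells, of which the anti-NKp46 library held 98, chaperone genes were higher and Spp1 was lower. Heat shock genes were higher in 5 of 10 (median 0.58, 0.47 to 0.75), with Hsph1 at 1.41 and Hspa8 at 0.84, and the chaperone partner Fkbp4 was at 1.46. The kinase Sgk1 (1.47), the interferon signal transducer Stat1 (1.13, 0.74 to 1.51), the translation repressor Eif4ebp2 (1.49), the histone demethylase Phf8 (1.37) and the deubiquitinase Usp19 (1.30) were also higher. Spp1 was lower, at 61.7 against 389.4 CPM (−2.66, −3.42 to −1.99), as were the costimulatory receptor Tnfrsf9 (−1.36), Phactr3 (−1.69), Alg5 (−1.85), Rbm3 (−0.92) and the glycoprotein Cd52 (−0.65). Spp1 was also lower in tubule-like cells, which are rich in it, at 935.3 CPM in 4 cells against 14746 CPM in 12 cells, and RNA released from such cells was not ruled out as part of its signal in NK-like cells. Of 10 effector cytokines and chemokines 3 were lower and 0 higher (median −0.12), and of 16 cytotoxic granule genes 1 was lower (−0.20). Ccl4 (−0.85), Ifng (−0.79, −1.36 to −0.26), Rgs1 (−0.81) and Xcl1 (−1.60) were lower. Gzma (0.33), Prf1 (−0.45), Gzmb (−0.37), Ccl5 (−0.13), Ccl3 (−0.30), Tbx21 (0.53), Eomes (0.14) and Itga2 (0.08) differed by less than 1.5-fold.

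Type I interferon response genes were higher in 1 of 24 measured in NK-like cells (median 0.24, 0.06 to 0.42), and interferon-gamma response genes in 0 of 22 (0.13). Circulating and mature NK genes were within 1.5-fold in all 15 (0.29), and cell cycle genes were higher in 3 of 13 (0.29), for example Hmgb2 (0.80). The ribosome-related AY036118 was higher in all 3 populations, with ratios of 1.95, 2.04 and 2.27, but it lies on chromosome 17 (39847113 to 39848035, minus strand) within Gm42418, so its reads may not be its own. The way of averaging and the definition of NK-like cells changed several of these values. The interferon median was 0.55 to 0.86 under 5 of the alternatives. The 0.55 was a mean of per-cell CPM over the same cells, and the others defined the cells in another way. Xcl1 was 0.36 with genes centred per library and 0.12 by marker score, and by that score Rgs1 was 0.19, Sgk1 0.04, Ccl4 −0.11 and Ifng −0.08.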

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

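The depth test of the cell shares, the test without NK-like cells, the handling test of the interferon genes, and the tests for single macrophages and free RNA were chosen only after the results were seen, as were the comparison with clusters weighted as in the isotype library and the restriction to cells of at least 2000 UMIs.

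Signals came also from features that the comparisons of the report do not use, namely unnamed or predicted genes and T cell receptor segments. Only features counted as higher with anti-NKp46 than with isotype in innate lymphoid cells were listed. The shared direction of these 7 was therefore fixed by the selection. The T cell receptor segments Trbc2 (106.9 against 43.3 CPM, log2 ratio 1.30) and Tcrg-C4 (122.8 against 61.2 CPM, 1.01) belong to families of similar sequence, so their counts per member are uncertain. The predicted genes were Gm26740 (58.7 against 22.5 CPM, 1.38), Gm36723 (76.8 against 34.4 CPM, 1.16), Gm11808 (256.3 against 128.2 CPM, 1.00), Gm42418 (8492 against 4551 CPM, 0.90) and 2900026A02Rik (81.2 against 53.6 CPM, 0.60). Gm42418 spans AY036118 on the opposite strand, and Gm36723 leads cluster 3, which came mostly from the anti-NKp46 library. No explanation was tested for these 7.

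The anti-NKp46 library had more ILC1-like and fewer NK-like cells. A difference in depth was argued against as the whole cause, since the ILC1-like difference was 30.1 percentage points after thinning to 1000 UMIs and new clustering. Shallow barcodes were argued against too, since it was 35.9 points among cells of at least 2000 UMIs. Those cells kept their clusters without new clustering. The cut left 353 of 940 isotype and 642 of 1052 anti-NKp46 ILC1-like cells, so the size of that difference also depends on the depth of each cluster. Carry-over of mature NK cells from blood should be reduced by the exclusion of cells reached by CD45.2 antibody in the blood, though how far was not measured. Without the NK-like cluster, ILC1-like cells were 63.8% of innate lymphoid cells with anti-NKp46 and 40.3% with isotype. That difference of 23.5 points (20.4 to 26.5) rests largely on cluster 3, which held 598 anti-NKp46 and 61 isotype cells. Cluster 3 may be that library rather than a cell type. The difference argues against less carry-over as the whole cause only if cluster 3 is taken as ILC1-like cells. The animals, kidneys and sort of each pool cannot be told apart from the antibody with 1 library per group. An effect of NKp46 blockade on kidney lymphocytes is therefore a hypothesis that stays open beside these.

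Interferon response genes were higher with anti-NKp46. Their median in ILC1-like cells was 0.75 with TMM factors. Over innate lymphoid cells the median was 0.88 with clusters weighted as in the isotype library. These values argue against scaling or the mix of clusters as the whole cause. After thinning, the ILC1-like median was 0.89. The ratios were already scaled to totals and the cells kept their classes, so thinning could change them little and depth stays open. The medians of cluster 1 and of NK-like cells were 1.42 apart, but these clusters were picked after the medians were seen. By marker score the ILC1-like and NK-like medians were 0.92 and 0.86, and with genes centred per library 0.91 and 0.82, so handling that moved every cell type alike stays open. Differences between pools and an effect of the antibody stay open too.

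Cells with macrophage transcripts were seen in a sort for NK1.1. Single macrophages were argued against as the whole source. In the isotype library 10 NK and ILC1 genes, pooled over the cluster, stood at a median of 64.4% of their level in innate lymphoid cells. Free RNA in all droplets was also examined. A UMI of C1qa, C1qb, C1qc or Lyz2 was in 387 isotype cells of any cluster (11.1%, 10.1 to 12.2), which is 12.1% of the number expected if these UMIs were spread by depth. These genes lead the macrophage-like cluster, so a low value followed from their choice. It shows that their UMIs were concentrated in few cells, and it does not measure the amount of free RNA. Pairs of a macrophage and a lymphocyte formed by chance would leave most of these barcodes without a UMI of the 10 genes. Such barcodes were 12.5% of the macrophage-like isotype cells (8.74 to 17.3) and 9.09% of the 22 anti-NKp46 ones (1.12 to 29.2). Chance pairs stay open, because the isotype value lay between the 2 bounds set for this test. Free RNA of the 10 genes, which was not measured, could also lower these shares. Attached or engulfed lymphocytes were not tested, and no biological explanation was tested.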

How the results depend on the processing

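Of the alternatives below, cluster 1 alone, cluster 3 alone, clusters weighted as in the isotype library and cells of at least 2000 UMIs were chosen only after the results were seen, as were innate lymphoid cells as the denominator, cells with macrophage UMIs left out and Csf2 without its 3 richest cells.

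The 13 leading results had 156 alternative values, of which 97 lay within the counting interval of the main value and 59 outside it, 58 of these with the same sign and 1 with the other. Of 2456 alternative values for 176 named genes and lists, 1845 lay within the interval, 516 were outside it with the same sign, 79 were outside it with the other sign for results not called higher or lower, and 16 had the other sign for results that were. These 16 are printed below as reversed, whatever their size. No paired analysis was possible because there was 1 library per group and the labels give no replicate numbers. The cause was not tested for any value below, save where the construction of the alternative is stated.

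With TMM factors the interferon median was 0.67 in innate lymphoid and 0.75 in ILC1-like cells, the heat shock median 0.53, the ILC1-like NF-kB median −0.57 and ILC1-like Ncr1 0.27. With totals that leave out ribosomal, mitochondrial and the 20 most abundant genes, heat shock was 0.60 and ILC1-like Ncr1 0.31. As a mean of per-cell CPM, Csf2 over innate lymphoid cells was −1.59, heat shock 0.78, ILC1-like Ncr1 0.36 and the NK-like interferon median 0.55, and the cell cycle median reversed to 0.11. Counting members from 5 CPM gave an innate interferon median of 0.95, and from 100 CPM an ILC1-like NF-kB median of −0.60.

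After thinning to 1000 UMIs, Csf2 was −1.096 over innate lymphoid and −2.16 in ILC1-like cells, heat shock 0.78, ILC1-like Ncr1 0.49 and the NK-like share −19.8 points. Cell cycle (0.10) and Itga2 in ILC1-like cells (0.37) reversed. Without thinning the share of ILC1-like cells with a Ncr1 UMI differed by 1.02 points, and at 2000 UMIs by 4.51 points, with −5.16 points for Csf2. With no filter on cells the NK-like share was −19.96 points and the NK-like interferon median 0.65. With the strict filter the NK-like share was −9.54 points and the ILC1-like interferon median 1.05. With doublets kept the ILC1-like share was 34.6 and the NK-like share −7.98 points, with ILC1-like Csf2 at −0.54 and NF-kB at −0.14.

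At resolution 0.3 the NK-like share was −11.1 points and the NK-like interferon median 0.63. At resolution 1.0 the ILC1-like share was 19.5 and the NK-like share −22.7 points. Clustered with list genes, the NK-like share was −21.1 points, ILC1-like Csf2 −0.70, NF-kB −0.21 and interferon 0.54, the NK-like interferon median 0.42, and Cxcl10 in ILC1-like cells reversed to −0.99. With genes centred per library the shares were 25.8 and −15.9 points, the NK-like interferon median 0.82, and NK-like Xcl1 reversed to 0.36. By marker score the shares were 21.4 and −15.6 points, ILC1-like NF-kB −0.19 and NK-like interferon 0.86, and in NK-like cells Rgs1 (0.19) and Xcl1 (0.12) reversed.

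In cluster 1 alone Csf2 was −1.74, Ncr1 0.26, NF-kB −0.086 and interferon 1.66. In cluster 3 alone, with 61 isotype cells, NF-kB was 0.044 and interferon 0.18, and Cd74 (0.63), H2-Aa (1.07), Cxcl10 (−2.44), Ifit3 (−0.67) and Itga1 (−0.43) reversed. Csf2 there had 0 isotype and 12 anti-NKp46 UMIs, so its value of −1.84, set against a floor of 3 UMIs in the isotype library, is a lower bound that leaves the direction open. With clusters weighted as in the isotype library Cd200r1 (−0.0041), Stmn1 (0.29), cell cycle (0.18) and circulating and mature NK genes (0.31) reversed, where by construction the mix of clusters was held fixed. Among cells of at least 2000 UMIs the ILC1-like share was 35.9 and the macrophage-like share −8.20 points, heat shock 0.62, interferon 0.97 in innate lymphoid and 1.05 in ILC1-like cells, and ILC1-like Ncr1 0.55. Of innate lymphoid cells, the NK-like share was −20.1 points.

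Depth limits the NK-like comparison, with 291650 UMIs in 98 anti-NKp46 cells.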

Other observations

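These T cell receptor complex and temperature-responsive genes were chosen only after their values were seen. Cluster 0 had Cd3g, a CD3 chain, at 1175 CPM (335 CPM in the other cells) and in 63.7% of its cells, while Cd3e, another CD3 chain, was at 11.2 CPM and in 0.926% of them. Cluster 4 had Cd3d at 243 CPM (65.8 CPM in the other cells) and Cd3g at 735 CPM, with Cd3e at 6.51 CPM in 0.867% of its cells, beside Tcf7 at 225 CPM and Eomes at 362 CPM. The T-like cluster 5 had Cd3e at 1852 CPM in 96.6% of its cells, Cd3g at 2473 CPM, Cd3d at 1102 CPM and Trac at 189 CPM.

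The cold-inducible RNA-binding gene Cirbp was lower with anti-NKp46 in innate lymphoid cells (log2 ratio −0.92, −1.07 to −0.77), as was Rbm3 (−1.72). In clusters 0, 1, 3 and 4 the Cirbp ratios were −0.99, −1.18, −1.06 and −1.42, and in NK-like cells −0.79. Over the same clusters Hspa8 had ratios of 1.11, 1.23, 1.27 and 1.18, and in NK-like cells 0.84. A difference in how the libraries were handled may account for these temperature-responsive genes. It was not tested, and the heat shock median of 0.69 over innate lymphoid cells was 0.53 with TMM factors and 0.78 after thinning to 1000 UMIs.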
